A study of Mus musculus with 4 samples.

How the data were processed

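Total RNA of 4 samples of EO771 mouse mammary carcinoma cells was sequenced, 2 labelled untreated and 2 labelled BML-210 (1.0 µM, 48 h). Per the labels' protocols, RNA was extracted with TRIzol and a miRNeasy kit, libraries were made with the KAPA RNA HyperPrep kit, and sequencing was paired-end on a NovaSeq instrument. The authors deposited 1 table of raw counts per gene, with the gene name, its versioned Ensembl identifier, exon coordinates, strand and exonic length per the file headers. The values are whole read counts with no normalisation. Per the submitters' processing notes, the tools include bcl2fastq, STAR 2.5, featureCounts from Subread 1.5.1 and edgeR 3.20.8, and the genome build is mm10. The settings for strand, multi-mapping reads and overlapping genes, and the gene annotation, are not given in the sources used here. Overlapping and antisense genes and near-identical families such as the histones are therefore uncertain one by one. All 4 columns of counts were matched to samples by the library names in the labels.

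Gene identifiers were compared with GENCODE release M21 for the same assembly: 98.3% matched without the version, and 99.5% of tested genes had the same start and end. That annotation gave gene classes, GC content and exon overlaps, and 5096 of the tested genes have an exon that overlaps one of another gene. The gene symbols and coordinates printed are those of the deposited counts table, in mm10.

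Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with default settings, which left 14455 of 56350 (23739 had no count in any library). Libraries were scaled by TMM, and the groups were compared with the quasi-likelihood test (glmQLFit with robust=TRUE, then glmQLFTest) on a design with the group alone, which leaves 2 residual degrees of freedom and shares the spread across genes. P-values were adjusted by Benjamini-Hochberg over all tested genes and called below 0.05. The standard error of a log2 fold change is its size over the square root of the F statistic, an approximation. CPM are counts scaled to the TMM-normalised library size, given as mean ± SD over 2 libraries. A count of 3 equals 0.181 to 0.228 CPM in single libraries, and such floors cover counting error only, because the reads carry no molecular identifiers.

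Before the data were examined, 35 gene lists (pathways, the drug's target family, genes with a known response to HDAC inhibitors, cell state and other cell types, RNA quality) were fixed. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists, and again with an estimated correlation. The estimated version refers its statistic to the 2 residual degrees of freedom, so few lists could pass it. A failure there says little about a list. The preset correlation is an assumption: where members of a list vary together more closely than that, its p-values are too small. Counts of genes within a list use the adjustment over all genes, and counts adjusted over the list alone are given beside them. The rule for named genes, also fixed then, takes the 8 largest rises and the 8 largest falls among genes called with a mean of at least 5 CPM, separated groups and a given symbol. It further takes each tested HDAC gene, up to 4 members with the smallest adjusted p per list, and up to 2 members that go against their list. Of the 173 genes that this rule names, 75 have an exon that overlaps one of another gene. Some genes that the rule takes are not reported here. Named outside the rule, after their values were seen, are Gm26917, Scn1a, Lyz2, Ptprc, C1qb, Tyrobp, Cd74, Hspa5, Pdia4 and Hsp90b1.

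Replicates were checked before averaging. Their counts differed by more than sampling noise (chi-square over its degrees of freedom 2.91 between the libraries labelled untreated and 1.81 between those labelled BML-210), so they were not pooled and each counts as 1 sample. Separate library preparations of 1 culture could also differ in this way, so the check does not show separate cultures. The coefficient of variation that edgeR calls biological was 2.49%, a spread that may be technical. The steps were tested on simulated data, with counts drawn from the real means and library sizes for 2 against 2 and 14333 genes tested: 62.6% of 99 genes changed by a log2 fold change of 0.5 and 84.5% of 97 changed by 1 were recovered, and 11 of 155 calls were false. Only 200 genes were changed there, against 6714 called in the data, so these shares need not hold for the data. The simulated spread was fitted to these same libraries, so it cannot show whether that spread is too small.

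Alternatives fixed before the data were examined were RLE, upper-quartile and no scaling factors, no filter or a mean of at least 1 CPM, the replicate number as a block, each library left out, genes with over 1% of a library's counts left out, DESeq2 1.42.0, limma-voom (limma 3.58.1), edgeR's likelihood ratio test, a non-robust dispersion, an adjusted p below 0.01, a test against a fold of 1.2, and list tests with an estimated correlation or without shared members. Chosen after seeing the data were counts thinned to the smallest library and removal of the trend with GC content and exonic length (loess, span 0.3). Groups of 2 are too small for an outlier test of single libraries.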

Results

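RNA was measured in EO771 cells, a mammary carcinoma cell line from C57BL/6 mice, after 48 h of culture with BML-210 at 1.0 µM or without it. Of the control cells the labels say both that they were untreated and that they received vehicle. BML-210 is a synthetic inhibitor of histone deacetylases (HDACs), the enzymes that remove acetyl groups from histones, and it also blocks the binding of class IIa HDACs to the transcription factor MEF2. The series holds 4 libraries of total RNA, 2 labelled untreated and 2 labelled BML-210. Gene counts summed to 16534667 and 13855061 in the libraries labelled untreated and to 13167893 and 13961743 in those labelled BML-210. Of 56350 annotated genes, 14455 had enough counts to be tested. The comparison asks which genes differ in expression between EO771 cells cultured with the HDAC inhibitor and those cultured without it. Every fold change below is that of the libraries labelled BML-210 over those labelled untreated.

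Genes of cell division and inflammation signalling were higher in the libraries labelled BML-210: 34 of 34 tested mitosis genes, 33 of 40 DNA replication genes, 27 of 27 replication-dependent histone genes and 19 of 21 NF-kappaB pathway genes. Lower were 28 of 34 lysosome and autophagy genes, 17 of 23 NRF2 and metallothionein stress genes, 19 of 30 glycolysis and hypoxia genes and 20 of 34 nuclear genes of oxidative phosphorylation. The camera test called all 8 of these lists (adjusted p of 0.000824 or less), but none with an estimated correlation between genes (adjusted p = 0.0835 to 0.347 with an estimated correlation). With 2 residual degrees of freedom the estimated version has little power. The macrophage and endosome glycoprotein gene Cd68 fell 5.22-fold, from 162 ± 4.08 to 31.1 ± 1.45 counts scaled to library size (CPM, SD, n = 2). In all, 6714 genes (46.4% of those tested) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3312 higher and 3402 lower. Most changes were small: the median absolute log2 fold change of the genes called was 0.41. A change of 2-fold or more was found for 966 genes, of which 340 were higher and 626 lower. Both libraries of 1 group lay beyond both of the other for 71.3% of tested genes, against 33.3% by chance.

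**Figure D1:**
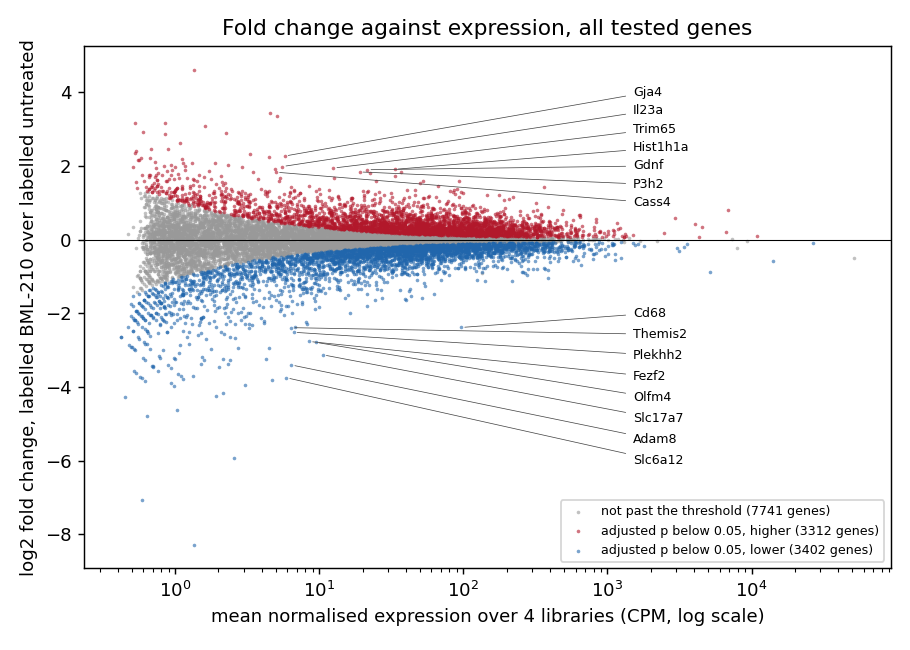
Log2 fold change of each tested gene (labelled BML-210 over labelled untreated) against its mean normalised expression over the 4 libraries in CPM on a log axis. Red and blue points are the 3312 higher and 3402 lower genes with an edgeR adjusted p below 0.05, grey points are the other tested genes, and the named points are genes with large changes and a mean of at least 5 CPM, from Gja4 (2.27) to Slc6a12 (-3.75).

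Among genes with a given symbol, separated groups and a mean of at least 5 CPM, the largest rises included that of Gja4, a connexin gene (ENSMUSG00000050234.7, chromosome 4, 127311421 to 127314039, mm10). It went from 1.93 ± 0.975 to 9.59 ± 0.0362 CPM (SD, n = 2), a log2 fold change of 2.27 ± 0.22 (SE; edgeR adjusted p = 3.57e-13). The cytokine subunit gene Il23a (1.98), Trim65 (1.94), the linker histone gene Hist1h1a (1.91), the neurotrophic factor gene Gdnf (1.90), the collagen prolyl hydroxylase gene P3h2 (1.84) and Cass4 (1.83) also rose. The largest fall was that of Slc6a12, a betaine and GABA transporter gene (ENSMUSG00000030109.15, chromosome 6, 121343076 to 121365775), from 11 ± 0.925 to 0.813 ± 0.242 CPM (SD, n = 2), a log2 fold change of -3.75 ± 0.25 (SE; edgeR adjusted p = 2.20e-19). The metalloproteinase gene Adam8 (-3.40), the vesicular glutamate transporter gene Slc17a7 (-3.13), Olfm4 (-2.79), the forebrain transcription factor gene Fezf2 (-2.76), Plekhh2 (-2.51) and Themis2 (-2.39) also fell. Cd68 (ENSMUSG00000018774.13, chromosome 11, 69664213 to 69666153) was the most abundant of the genes just named, and its log2 fold change was -2.38 ± 0.06 (SE; edgeR adjusted p = 7.62e-41). Exons of P3h2, Cass4, Adam8, Plekhh2, Trim65 and Olfm4 overlap an exon of another gene, and how shared reads were counted is not given in the sources used here.

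All 27 tested replication-dependent histone genes, which are expressed in S phase, were higher, 23 of them by 2-fold or more. Hist1h4d went from 195 ± 11.4 to 528 ± 19.4 CPM (SD, n = 2; log2 fold change 1.44, edgeR adjusted p = 2.55e-40), Hist1h1d from 137 to 307 CPM and Hist1h1e from 236 to 412 CPM. Members of this family are near-identical in sequence, so the count of a single member is less certain than that of the family. How reads that match several members were counted is not given. If they were shared, the members are not separate observations, and the number of genes called and the list p-value overstate the evidence. All 34 mitosis genes rose, with a median log2 fold change of 0.59: cyclin A2 (Ccna2) by 1.11 on the log2 scale, topoisomerase Top2a by 0.71, the spindle gene Tpx2 by 0.67 and the checkpoint gene Mad2l1 by 0.86. Of 40 DNA replication genes, 33 rose and 7 did not pass (median 0.54). The polymerase gene Pole (1.31), the helicase genes Mcm3 (0.91) and Mcm2 (0.90) and the ribonucleotide reductase gene Rrm1 (0.75) rose most clearly. In the list of MYC targets and ribosome biogenesis genes, 22 of 30 were higher and 2 lower (median 0.24). They include the nucleolar genes Nop56 (0.79), Nop58 (0.61) and Dkc1 (0.73) and Myc itself (0.36), while Ldha fell by 0.17. Adjusted over the list alone, the counts of these 4 lists were the same. The camera test called each list higher, with an adjusted p of 5.85e-52 for histones, 4.25e-31 for mitosis, 4.42e-18 for replication and 1.50e-09 for MYC targets. These values rest on the preset correlation and are too small if members of a list vary together more closely. None of the 4 calls holds with an estimated correlation between genes (adjusted p = 0.0835 for each with an estimated correlation). That version rests on 2 residual degrees of freedom and could hardly call any list, so it does not decide between them.

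**Figure D2:**
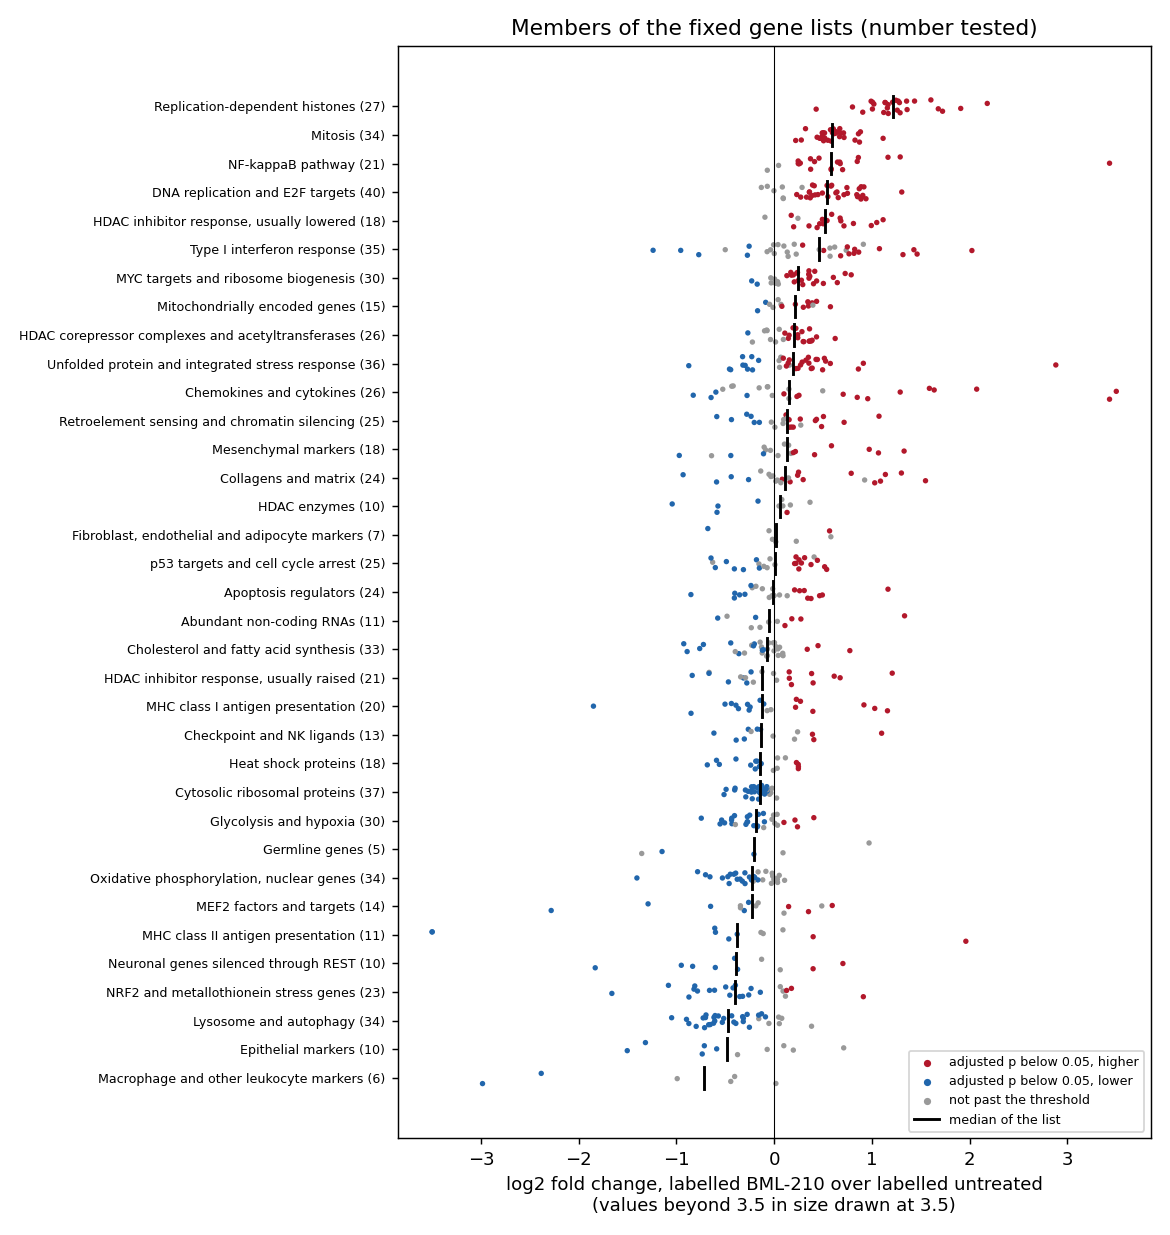
Log2 fold change (labelled BML-210 over labelled untreated) of every tested member of the 35 gene lists, ordered by list median. Each point is a gene, coloured by its edgeR call, the black bars are list medians, and values beyond 3.5 in size are drawn at 3.5. The medians run from -0.72 for leukocyte markers to 1.21 for the histone genes.

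Among the HDAC enzymes, Hdac11 fell by 1.04, Hdac6 by 0.59 and Hdac5 by 0.58 on the log2 scale (edgeR adjusted p = 5.08e-07, 5.16e-05 and 2.51e-13). Hdac1 (-0.17) and Hdac7 (0.13) passed with small changes. Both calls depend on single libraries: the adjusted p of Hdac1 was 0.0771 without untreated replicate 2 and 0.14 without BML-210 replicate 1, and that of Hdac7 was 0.177 without untreated replicate 1 and 0.206 without BML-210 replicate 1. Over 19 alternatives the adjusted p ran from 0.00184 to 1 for Hdac1 and from 1.25e-05 to 1 for Hdac7. Hdac3 (0.05), Hdac4 (0.08) and Hdac8 (0.17) did not pass. Hdac2 (0.09) and Hdac10 (0.37) did not pass, but Hdac2 did without untreated replicate 2 (adjusted p = 0.0204, 0.0204 to 1 over the alternatives) and Hdac10 did without untreated replicate 1 (0.0274) and with the GC and length trend removed in all 4 libraries (0.0271, with a range of 0.0271 to 0.449 over the alternatives). Of 26 genes of HDAC corepressor complexes and acetyltransferases, 17 were higher and 1 lower (17 and 3 adjusted over the list alone, median 0.21, camera adjusted p = 0.000712, and adjusted p = 0.225 with an estimated correlation). The remodeller gene Chd3 (0.62), the acetyltransferase genes Crebbp (0.43) and Kat6a (0.39) and the corepressor gene Ncor1 (0.36) were higher, and Rcor1 fell by 0.27.

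The list of genes usually lowered by HDAC inhibitors was higher in the libraries labelled BML-210, and that of genes usually raised was called in neither direction. Of 18 genes usually lowered by HDAC inhibitors, 16 were higher and 0 lower (median 0.52, the same counts adjusted over the list alone, camera adjusted p = 2.76e-11, and adjusted p = 0.0835 with an estimated correlation), among them the ribonucleotide reductase gene Rrm2 (0.59). The mitosis or replication list also holds 8 of these 18 genes. Of 21 genes usually raised, 8 were higher and 6 lower (8 and 8 adjusted over the list alone), and the list was not called (camera adjusted p = 0.202, with an upward direction although the median was -0.12 and the mean -0.03). The linker histone gene H1f0 rose from 497 ± 10.3 to 793 ± 2.63 CPM (SD, n = 2), and the coactivator gene Cited2 (1.21) and Hist1h1c (0.61) rose as well. The polyamine acetyltransferase gene Sat1 (-0.84), Clu (-0.47) and the cell cycle inhibitor gene Cdkn1a (-0.32) fell. Every direction given here rests on the group labels. The library codes beside them, D for the libraries labelled untreated and V for those labelled BML-210, leave open whether the groups were exchanged.

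**Figure D3:**
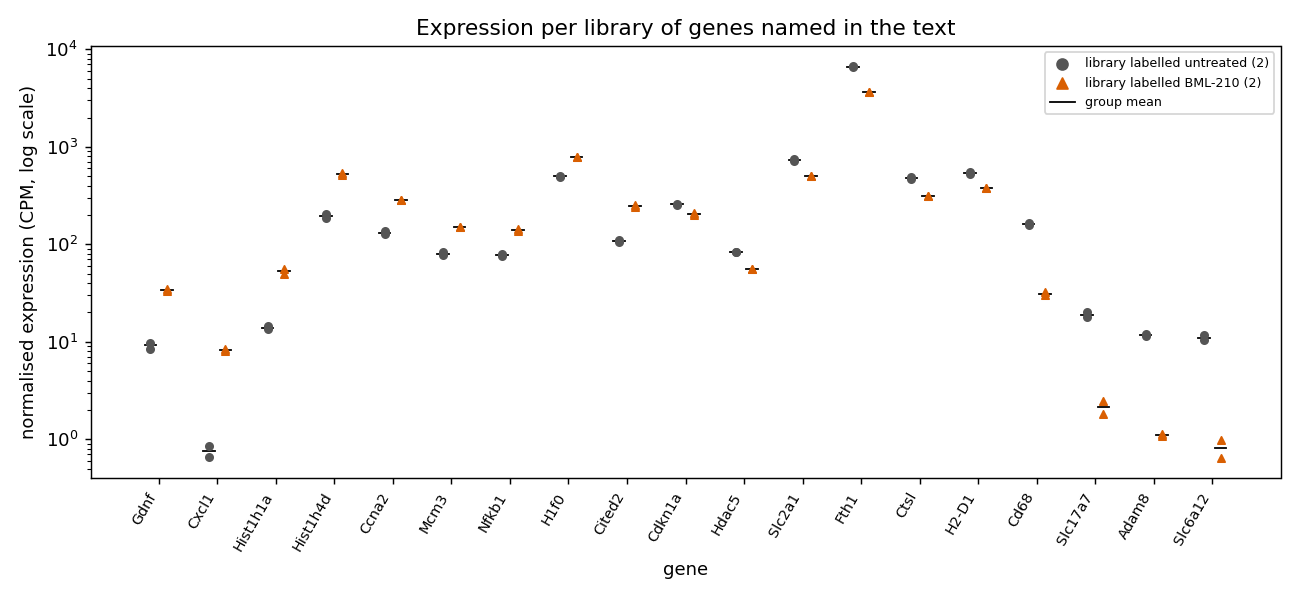
Normalised expression in CPM (log axis) of 19 genes in each of the 4 libraries. Grey circles are the 2 libraries labelled untreated, orange triangles the 2 labelled BML-210 and short lines the group means, for example 162 and 31.1 CPM for Cd68.

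NF-kappaB pathway genes were higher in 19 of 21 cases and lower in 0 (median 0.58, the same counts adjusted over the list alone, camera adjusted p = 6.53e-14, and adjusted p = 0.0835 with an estimated correlation). The subunit gene Nfkb1 rose from 77.0 ± 2.85 to 140.2 ± 4.91 CPM (SD, n = 2), and the inhibitor gene Nfkbia (0.58) and Nfkbiz (0.65) rose with it. Among 26 chemokine and cytokine genes, 12 were higher and 4 lower (the same adjusted over the list alone, median 0.15, camera adjusted p = 0.00454, and adjusted p = 0.347 with an estimated correlation). The monocyte chemoattractant genes Ccl2 (0.85) and Ccl7 (0.96), Tnf (1.59) and the neutrophil chemoattractant gene Cxcl1 (3.43, from 0.754 to 8.31 CPM) rose, while Tgfb1 (-0.28) and Lif (-0.60) fell. Without the members that other lists also hold, the median of the chemokine list turned to -0.02 and its adjusted p was 0.228 (0.00229 to 0.228 over 14 alternatives, the estimated correlation aside).

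Of 35 type I interferon response genes, 13 were higher, 5 lower and 17 did not pass (14 and 5 adjusted over the list alone, median 0.46, camera adjusted p = 0.0455, and adjusted p = 0.284 with an estimated correlation). The interferon regulatory factor genes Irf1 (0.68) and Irf9 (1.46), Ifit1 (1.43) and Parp14 (0.82) rose, and the viral RNA sensors Oas3 (-1.24) and Dhx58 (-0.77) fell. The call of this list ended without untreated replicate 1 (adjusted p = 0.0857), with library size only (0.052) and with a mean of at least 1 CPM (0.0616), with a range of 0.00023 to 0.0857 over 14 alternatives. MHC class I genes went both ways, with 7 higher and 11 lower of 20 (the same adjusted over the list alone, camera adjusted p = 0.292). The heavy chain gene H2-D1 fell from 542 ± 22.2 to 382 ± 0.348 CPM (SD, n = 2) and the light chain gene B2m from 1042 to 878 CPM, while the peptidase gene Erap1 (1.03) and the immunoproteasome gene Psmb10 (1.16) rose. In the MHC class II list, 6 of 11 genes were lower and 2 higher (the same adjusted over the list alone, median -0.38 with H2-Eb1 at its fitted value or at the bound below, camera adjusted p = 0.0458, and adjusted p = 0.347 with an estimated correlation). H2-Aa fell from 3.66 to 0.185 CPM, the latter at the level of about 3 counts in a library. H2-Eb1 had 35 counts over the libraries labelled untreated and 0 over those labelled BML-210, at least 10.4-fold lower when set against a floor of 3 counts over the group. Ctsl (-0.61) and H2-DMa (-0.46) fell too, and the regulator gene Rfx5 (0.40) and H2-Oa (1.96, from a low 0.413 to 1.58 CPM) rose. The class II call ended without untreated replicate 1 (adjusted p = 0.0538, median -0.27, 4 lower), without BML-210 replicate 2 (0.083, median -0.24, 4 lower), with upper-quartile scaling (0.0524), with thinned counts (0.0677) and without the members that other lists hold (0.31), with a range of 0.00804 to 0.31 over 14 alternatives.

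Lysosome and autophagy genes were lower in 28 of 34 cases and higher in 0 (29 lower adjusted over the list alone, median -0.48, camera adjusted p = 1.92e-20, and adjusted p = 0.0835 with an estimated correlation). The protease genes Ctsd and Ctsb fell from 350.0 ± 3.87 to 188 ± 6.82 CPM and from 809.6 ± 8.10 to 499 ± 13.2 CPM (SD, n = 2), and the proton pump gene Atp6v0a1 had a log2 fold change of -0.87. NRF2 and metallothionein stress genes were lower in 17 of 23 cases and higher in 3 (17 and 4 adjusted over the list alone, median -0.40, camera adjusted p = 5.19e-11, and adjusted p = 0.0835 with an estimated correlation). The ferritin genes Fth1, from 6673 ± 214 to 3644 ± 15.2 CPM (SD, n = 2), and Ftl1 (-0.82) fell, as did the sulfiredoxin gene Srxn1 (-1.08). The cystine transporter gene Slc7a11 (0.91) and Mt2 (0.18) rose.

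Of 30 glycolysis and hypoxia genes, 19 were lower and 4 higher (20 and 4 adjusted over the list alone, median -0.19, camera adjusted p = 9.62e-07, and adjusted p = 0.109 with an estimated correlation). The glucose transporter gene Slc2a1 fell from 737 ± 21.5 to 502 ± 3.74 CPM (SD, n = 2), and the glycolytic enzyme genes Aldoa (-0.51), Hk1 (-0.54) and Pkm (-0.43) fell, whereas Pdk1 (0.21) and Pfkl (0.24) rose. Nuclear genes of oxidative phosphorylation were lower in 20 of 34 cases and higher in 0 (20 and 1 adjusted over the list alone, median -0.22, camera adjusted p = 0.000824, and adjusted p = 0.347 with an estimated correlation), including Sdhc (-0.70) and Cox7b (-0.66). In the pooled list of unfolded protein and integrated stress response genes, 22 of 36 were higher and 10 lower (23 and 10 adjusted over the list alone, median 0.19, camera adjusted p = 0.00202, and adjusted p = 0.367 with an estimated correlation). Herpud1 (0.86), Shmt2 (0.51) and Cebpb (0.50) rose, and the chaperone genes Pdia6 (-0.45) and Calr (-0.27) fell. The chaperone genes Hspa5 (-0.22) and Pdia4 (-0.32) fell as well, while Hsp90b1 (0.12) rose. The direction of the list is therefore not that of most of these chaperone genes.

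Collagen and matrix genes were higher in 11 of 24 cases and lower in 4 (the same adjusted over the list alone, median 0.11, camera adjusted p = 0.00466, and adjusted p = 0.253 with an estimated correlation). The collagen VI genes Col6a1, from 122 ± 3.26 to 259 ± 2.08 CPM (SD, n = 2), and Col6a2 (1.30) rose, and Nid1 (-0.44) and Col5a1 (-0.26) fell. Of 18 mesenchymal markers, 7 were higher and 3 lower (the same adjusted over the list alone), and the list was not called (camera adjusted p = 0.0759), although it was without BML-210 replicate 2 (adjusted p = 0.0288) and with the GC and length trend removed (0.0451), in a range of 0.0288 to 0.208 over 14 alternatives. The gelatinase gene Mmp9 (1.33), Prrx1 (0.97) and Zeb2 (0.59) rose, and the integrin genes Itgb3 (-0.97) and Itga5 (-0.44) fell. Epithelial markers were lower in 5 of 10 cases and higher in 0 (the same adjusted over the list alone), and the list was not called (camera adjusted p = 0.0781), although it was called lower without a filter on low counts (0.0369, in a range of 0.0369 to 0.121 over 14 alternatives). The transcription factor gene Grhl2 (-1.50) and keratin 8 (Krt8, -0.59) fell. Neuronal genes under the repressor REST, which recruits HDACs, were lower in 6 of 10 cases and higher in 2 (the same adjusted over the list alone, median -0.39, camera adjusted p = 0.00683, and adjusted p = 0.347 with an estimated correlation). The adhesion gene L1cam fell from 362 ± 0.568 to 187 ± 7.04 CPM (SD, n = 2), and Unc13a (-0.83) and Syn1 (-0.41) fell, while Vgf (0.70) rose.

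Markers of other cells and of RNA quality also differed between the groups. Of 6 tested leukocyte markers, Cd68 and Adgre1 (-2.98, from 1.48 to 0.181 CPM) were lower and 4 did not pass (the same adjusted over the list alone, median -0.72, camera adjusted p = 3.54e-05, and adjusted p = 0.161 with an estimated correlation). This call ended without a filter on low counts (adjusted p = 0.0722, in a range of 2.88e-05 to 0.0722 over 13 alternatives). Cytosolic ribosomal protein genes were lower in 32 of 37 cases and higher in 0 (the same adjusted over the list alone, median -0.14, camera adjusted p = 9.62e-07, and adjusted p = 0.249 with an estimated correlation), with Rpl38 at -0.49 and Rpl8 at -0.27. Mitochondrially encoded genes were higher in 8 of 15 cases and lower in 2 (the same adjusted over the list alone, median 0.22, camera adjusted p = 0.00607, and adjusted p = 0.249 with an estimated correlation), led by mt-Cytb (0.58). Their call ended when the trend with GC content and gene length was removed (adjusted p = 0.386, and 3.27e-05 to 0.386 over 14 alternatives). Mitochondrial genes took 5.4% and 5.05% of counts in the libraries labelled untreated and 5.57% and 5.41% in those labelled BML-210. The non-coding gene Gm26917, which is outside the rule for named genes, took 5.52% and 6.41% against 4.04% and 4.45%, and Malat1 1.68% and 1.64% against 1.13% and 1.13%.

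Of the 35 lists, camera called 12 higher and 8 lower at its preset correlation of 0.01, and 0 with an estimated correlation. The preset value was assumed, and p-values from it are too small for lists whose members vary together more closely. The estimated version has little power with 2 residual degrees of freedom, so its 0 calls leave open which lists would hold. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of genes called depends on the test, with 4335 by DESeq2 and 2990 in edgeR's test against a fold of 1.2.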

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

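Thinning to the smallest library and removal of the GC and length trend were chosen after seeing the data. Against 6714 changed genes (3312 higher, 3402 lower), DESeq2 called 4335 (2205 and 2130), with 626 at 2-fold or more (206 higher) in place of 966 (340 higher). A test against a fold of 1.2 called 2990 (1385 higher, 1605 lower), fewer because it asks for a larger change. Each other setting gave counts of genes within 1.5 times the main ones. Genes called in both settings kept their direction in all settings except removal of the GC and length trend, where 6024 of 6025 did. Upper-quartile scaling moved the share of higher genes among calls from 49.3% to 44%. Leaving out each library in turn gave 5655 to 5908 changed genes and 18 to 20 lists, with 80.4% to 84% of the calls kept. The replicate block gave 6847 changed genes and 19 lists. Its call of the interferon list ended (adjusted p = 0.0533). Same-numbered libraries did not deviate together (correlation across genes 0.0155), so the numbers were not taken to pair the samples. With an estimated inter-gene correlation 0 of 20 lists were called, the lowest adjusted p being 0.0835, in a test with little power at 2 residual degrees of freedom. Calls of the interferon, MHC class II, chemokine, leukocyte and mitochondrially encoded lists ended in the settings named in the report, each in the same direction by the test. Removing the GC and length trend called the list of genes usually raised by HDAC inhibitors upward (median -0.06, mean 0.01, adjusted p = 0.0238, and 0.0238 to 0.806 over 14 settings). The cause of these differences was not tested. Depth limits low genes most: 3 counts are 0.181 to 0.228 CPM.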

Other observations

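The tests of RNAs without a poly(A) tail, of S phase genes and of leukocyte markers were chosen after the results they bear on had been seen, and those of the group labels and of matched genes before.

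Genes of cell death, cell cycle arrest and stress went both ways. Of 25 p53 target and arrest genes, 11 were higher and 7 lower (the same adjusted over the list alone, camera adjusted p = 0.492): Zmat3 (0.54) and Sesn2 (0.44) rose, and Plk3 (-0.65) fell with Cdkn1a (-0.32). Of 24 apoptosis regulators, 8 were higher and 6 lower (the same adjusted over the list alone, adjusted p = 0.912), with the survival genes Birc3 (1.16) and Birc5 (0.49) up and Bcl2l1 (-0.35) and the death gene Bmf (-0.85) down. Heat shock genes were lower in 10 of 18 cases and higher in 4 (10 and 5 adjusted over the list alone, adjusted p = 0.196), where Hspa8 (-0.39) fell and the mitochondrial chaperone genes Hspd1 (0.25) and Hspe1 (0.23) rose. Among 13 checkpoint and NK ligand genes, 3 were higher and 6 lower (4 and 6 adjusted over the list alone, adjusted p = 0.881): the costimulator gene Icosl (1.10) and Cd47 (0.41) rose, and the poliovirus receptor genes Pvr (-0.27) and Nectin2 (-0.39) fell. MEF2 factors and targets were higher in 3 of 14 cases and lower in 5 (the same adjusted over the list alone, adjusted p = 0.149), with the nuclear receptor gene Nr4a3 at -2.28 and Mef2d at -0.26.

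Chromatin silencing and retroelement sensing genes were higher in 12 of 25 cases and lower in 6 (14 and 6 adjusted over the list alone, camera adjusted p = 0.241, and 0.0135 to 0.367 over 14 alternatives, the lowest without a filter): the methyltransferase genes Dnmt1 (0.42) and Suv39h2 (1.07) rose, and Tet2 (-0.59) fell. Cholesterol and fatty acid genes were lower in 10 of 33 cases and higher in 3 (the same adjusted over the list alone, adjusted p = 0.406), with Dhcr7 (-0.72) down and Fasn (0.34) up. Of 5 tested germline genes, 2 were lower (3 adjusted over the list alone, adjusted p = 0.708), and 1 of 7 fibroblast, endothelial and adipocyte markers was higher, Pdgfrb (0.57), and 1 lower, Pdgfra (-0.68; the same adjusted over the list alone, adjusted p = 0.881). Abundant non-coding RNAs were higher in 4 of 11 cases and lower in 2 (the same adjusted over the list alone, adjusted p = 0.613), with Malat1 at -0.58 and Neat1 at 0.18. Of the tested genes, 2 had counts in 1 group alone. They are H2-Eb1 and the sodium channel gene Scn1a, named after its values were seen, which had 81 counts in the libraries labelled untreated and 0 in those labelled BML-210 (at least 24.1-fold lower against 3 counts over the group). Over the 20 chromosomes tested, the median log2 fold change of genes with at least 5 CPM lay between -0.03 and 0.06.

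The labels give the direction of every change, and the library codes beside them hold letters that could belong to the other group. The codes have D for the libraries labelled untreated and V for those labelled BML-210. What the letters stand for is not stated: V could be vehicle and D drug, or D could be a solvent. If the labels were exchanged, the genes usually raised by HDAC inhibitors would be lower in the libraries labelled BML-210, with a median below 0 and more members called lower than higher. Their median was -0.125, but 8 were called higher and 6 lower, and with the GC and length trend removed camera called the list upward (adjusted p = 0.0238) at a median still below 0 (-0.06, 8 higher and 7 lower), so this test leaves the labels open. Genes usually lowered went against the labels in 16 of 18 cases, and Cdkn1a fell, while H1f0 rose with the labels. Other lists tied to HDACs also held more lower than higher genes, though they were not part of this test. Neuronal genes under REST were lower in 6 of 10 cases and higher in 2 (camera adjusted p = 0.00683). MEF2 factors and targets were lower in 5 of 14 and higher in 3, and germline genes lower in 2 of 5 and higher in 0, with neither list called. An exchange and a response of these cells at this dose that departs from the usual one both stay open, and their relative weight was not tested.

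All 27 tested replication-dependent histone genes were higher, and 51 of 55 tested genes of the histone clusters were, though reads shared among near-identical members could tie these calls together. Genes matched in GC content and length had a median log2 fold change of -0.092 (240 genes, upper quartile 0.10), far below the histone median of 1.21, although the match was loose (median GC 48.8% against 54.5%, median length 1271 against 704 bases). Other RNAs without a poly(A) tail, 131 small nuclear, nucleolar and Cajal body RNAs, had a median of -0.0071 and an upper quartile of 0.34, which argues against better recovery of such RNAs as a whole. A hypothesis in line with the replication genes (median 0.54, 33 higher and 0 lower of 40) is that more cells were in S phase in the cultures labelled BML-210. Those genes rose less than the histones, and all 34 tested mitosis genes rose too (median 0.59), so these values do not single out S phase. No measure of the cell cycle other than RNA was used.

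Cd68 was 162 CPM in the libraries labelled untreated and 31.1 CPM in those labelled BML-210. Leukocytes in the cultures labelled untreated would bring their other abundant transcripts at a like level, but the highest other marker there was Lyz2 at 3.16 CPM (library size only), 1.96% of the Cd68 level, which argues against them as the source of most Cd68 reads. Other values go with the explanation: the macrophage gene Adgre1 fell with Cd68 (46 to 5 counts over the group, log2 fold change -2.98), C1qb went from 17 to 3 counts, and H2-Aa fell. Ptprc (22 and 20 counts), Tyrobp (3 and 3 counts) and the class II gene Cd74 (6.56 and 6.99 CPM) did not move with them. Whether a small number of leukocytes accounts for the rare transcripts that fell stays open. No exon of another gene overlaps Cd68, and no biological explanation for its fall was tested.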
